A study of Ovis aries with 5 samples.

How the data were processed

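Total RNA from sorted skin lymph dendritic cells (DC) of sheep was measured on 5 Agilent 2-colour arrays of 60-base probes, all on 1 slide. Per the labels, RNA was extracted with the Qiagen RNeasy Micro kit, 200 ng were amplified, and samples were labelled with Cy3 and the common reference with Cy5 using a Bioprime labelling kit. No dye swap was made: the sample was always Cy3. The groups, taken from the labels, are CD1b+CD26+ and CD1b+CD26- cells with 2 arrays each, from sheep 10081 and 30066, and 1 self-hybridisation of the reference. The sample labels call the reference total enriched lymph DC from other sheep, while the labelling protocol names RNA of a cultured cell line. On the self-hybridisation array the log2 Cy3 and Cy5 signals correlated with r = 0.992, and the Cy5 signals of any pair of arrays with r of at least 0.987, so no array stood apart in its Cy5 signal. It is called total DC here, as the sample labels do. The arrays of sheep 30066 lay in the slide row of the self-hybridisation and those of sheep 10081 in the other row, so that sheep and slide row cannot be told apart. There was no second slide or scan to test as a batch.

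The deposited array files hold spot intensity on a linear scale, not normalised, with local background, as read by Feature Extraction 9.5.3.1, per the file headers. Their log ratio of processed signals is a log10 value, per the file headers. A deposited value table holds a log2 ratio per spot. It equalled the negative of the scanner's log10 ratio divided by log10 of 2, to within 5e-10, so it is Cy3 over Cy5 and is not an independent alternative to the scanner's processed signals. Its column medians lay between -0.068 and 0.015, and no further centring by the authors is stated. Within each array the processed signals of the 2 dyes held the same sorted values, within 0.5 of the mean of the sorted median spot signals, which means that the scanner software had equalised the distributions of the dyes without subtracting background.

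Mean spot signals were corrected for local background with the normexp model and an offset of 50, normalised within each array by loess, and expressed as log2 of Cy3 over Cy5 with no scaling between arrays (limma 3.58.1 in R 4.3.3). The 536 control spots had weight 0 in loess and were left out, as were outlier-flagged spots (49 to 157 per array). Spots of the same probe were averaged.

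The way the normexp model was fitted was chosen after results had been seen. A first fit used all spots. On 4 of the arrays it was governed by up to 9 spots that lie beside bright specks, with a local background of up to 56118 units against medians of 36.5 to 52.5. Their corrected values lay far below 0, and the fitted model raised the dimmest hundredth of spots to between 57.6 and 1176 units depending on the array and dye, which compresses log ratios unequally. In the values reported here the model was fitted without spots whose local background exceeded 5 times the median of their array in either dye (0 to 9 per array), and these spots were left out. The dimmest hundredth then lay between 55 and 66.8 units. The limit of 5 was also set after results had been seen, and after another rule, leaving out every spot that the scanner marked for uneven background, had been tried and dropped because it removed many bright probes. The fit on all spots is kept as an alternative. Its values are given for every named gene that it moved by more than 1.5 times: 11 of 44 between the subsets, 0 of 22 for CD26+ and 8 of 24 for CD26- cells against total DC. On simulated arrays a 4-fold difference had a median estimate of 1.65 on the log2 scale with the reported fit and 1.22 with the fit on all spots.

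Of 15008 distinct probes, the 13264 well above background in Cy3 on at least 2 of the 5 arrays were tested, and 1744 were left out as dim. Before correction the median Cy3 signal was 204 to 307 units over a background of 36.5 to 39. The number of arrays limits the precision of every value. Genes were named from the files and from a table of sheep RefSeq genes (assembly ARS-UI_Ramb_v3.0, used for names only). A symbol was found for 1439 probes of 828 genes, of which 695 were tested; 13569 probes, mostly expressed sequence tags, have no gene name here. For PFKL, MYLK, NRP1 and CD1B the name was assigned after values had been seen. A gene with several probes is represented by the probe with the highest mean intensity. No genome was used, so positions of genes are not given.

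limma's lmFit and eBayes fitted 3 group means to the 5 arrays (2 residual degrees of freedom and 2.36 prior degrees of freedom), with calls at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes. The arrays of 2 sheep are biological replicates. The comparisons were CD26+ against CD26-, and each subset against total DC with the self-hybridisation as control. The subsets of a sheep are paired by the labels; the deviations of its 2 arrays from the group means correlated with r = 0.33. The fit without the replicate block was the main design, and the fit with the sheep as a block, which gave 1126 probes at an unadjusted p under 0.05 against 748, the alternative. The number of probes at least 2-fold apart in both sheep was counted without a test. For FST, not well above background on any CD26+ array, the fold is a bound from Cy3 values after loess and Aquantile scaling, open to dye bias since no dyes were swapped. For BMP7 against total DC this value exceeded the fold of the log ratios, so neither a bound nor a size is given. Ranges leaving out 1 array are given for every named gene that this moved by more than 1.5 times: 18 of 44 between the subsets, 2 of 22 for CD26+ and 4 of 24 for CD26- cells against total DC.

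Gene lists (24 lists, 755 entries, of which 138 were measured) covered DC subsets, other cell types that lymph or the gate could hold, antigen presentation, maturation, receptors and cell state. The 17 lists with at least 3 measured members were tested on CD26+ against CD26- with camera at a preset correlation of 0.01, camera with an estimated correlation and fry, adjusted over the lists. 1 list passed the first and 0 passed the others. The mitochondrial respiratory chain list had 0 measured members. The named genes are, per comparison, the 12 with the largest rise and the 12 with the largest fall among called genes, with free places given to the largest differences of at least 2-fold in both sheep (6 per direction against total DC), up to 4 members per list with the largest differences, DPP4 and CD1B. 1 gene that the rule picked for CD26+ against CD26- is not reported here, and its place was not refilled. Groups, design, lists, this rule and the first group of alternatives below were fixed before the data were examined. Members of the class II list named in addition were chosen after their values were seen.

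The alternatives were no background subtraction, the scanner's processed signals, the deposited table, median spot signals, median centring in place of loess, Aquantile scaling, no filter or a stricter filter on dim probes, an intensity trend in eBayes, the sheep as a fixed or random block, outlier spots kept, each array left out in turn, and the mean log ratio against 0. Added after the data had been seen were the fit of normexp on all spots, the removal of a departure shared by the subset arrays and the removal of a trend on probe GC content. The procedure was tested on simulated intensities built on the real reference signals, with 200 probes set apart by known folds. For CD26+ against CD26- over 13264 probes with the fitted spread, 0 of 50 probes were called at each of 2-fold, 4-fold, 8-fold and 16-fold, with 2 false calls among 13053 unchanged probes; 10, 33, 46 and 48 of 50 were at least 2-fold apart in both sheep. With a spread of 0.25 times the fitted one, 30, 46, 46 and 49 of 50 were called, with 12 false calls. A list shifted by 1 on the log2 scale was found by camera with the preset correlation (adjusted p = 0.000300) and not with an estimated one (0.951). Figures were drawn with matplotlib 3.10.9.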

Results

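Gene expression was compared between subsets of dendritic cells (DC), the antigen-presenting cells that leave the skin through the lymph, in sheep. Lymph DC had been sorted into CD1b+CD26+ and CD1b+CD26- cells. CD1b presents lipid antigens, and CD26 (dipeptidyl peptidase 4) is a cell surface protease. Both subsets came from the same 2 sheep, numbered 10081 and 30066, which gave 2 arrays per subset. On each of these 4 arrays the sorted cells were labelled with Cy3 and hybridised against a common Cy5 reference of total enriched lymph DC from other sheep. 1 further array carried that reference in both dyes and is called the self-hybridisation. Each array held 15008 distinct probes, of which 13264 were bright enough to be tested, and 828 genes could be named. The probes well above background in Cy3 made up 81.1% to 89.5% of each array. The log2 ratio of sample over reference had an SD of 0.29 over the tested probes on the self-hybridisation and of 1.18 to 1.42 on the subset arrays. The share of probes at least 2-fold from the reference was 0.969% on the self-hybridisation and 31.8% to 40.6% on the subset arrays. The number of arrays limits the precision of every value below.

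The first comparison set CD26+ against CD26- DC. CD26+ cells had higher values for chains of MHC class II, which present peptides to helper T cells, and for the cytokine gene IL12B. CD26- cells had higher values for the inflammatory mediators CXCL8 and IL1B and for the RNA receptor TLR8. No single gene passed the test, and the values below are given as sizes. DYA, a chain of the ruminant MHC class II molecule DY, was higher in CD26+ cells by 5.27 on the log2 scale (n = 2 sheep), 5.14 in sheep 30066 and 5.39 in sheep 10081. DYA was well above background on 2 of 2 CD26+ arrays and on 1 of 2 CD26- arrays, and stood at 3.67 with the background model fitted on all spots, in place of leaving out those beside bright specks. IL12B, the p40 chain of interleukin 12 and interleukin 23, was higher in CD26+ cells by 3.90 (SE 0.63), 4.49 in sheep 30066 and 3.31 in sheep 10081. Further genes higher in CD26+ cells were the growth factors BMP6 by 3.11 (SE 0.82) and BMP7 by 2.29 (SE 0.45). The remaining genes of this group on this side were MAPKAP1, a subunit of mTOR complex 2, at 2.43 (SE 0.33), the adenosine receptor ADORA3 at 2.32 (SE 0.34), CD1, a lipid antigen-presenting molecule, at 1.78 (SE 0.38), the cytokine IL1A at 1.75 (SE 0.36) and the oxidase XDH at 1.59 (SE 0.35). The class II chains DQA1 and DQA2 stood at 1.72 (SE 1.84) and 1.57 (SE 0.73). Every SE given here comes from the fit without the sheep as a block and so includes differences in level between the sheep.

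The genes with the largest differences in the other direction, lower in CD26+ than in CD26- cells, were MYLK, the myosin light chain kinase, at -3.41 (SE 1.30), and NPC2, a cholesterol carrier of lysosomes, at -2.82 (SE 0.51). The difference of MYLK ranged from -5.36 in sheep 30066 to -1.46 in sheep 10081. CTNNBL1 stood at -2.35 (SE 0.53), and FLT3LG, the ligand of the DC growth factor receptor FLT3, at -2.27 (SE 0.68). FST, which binds activins, was not well above background on the CD26+ arrays and was at least 4.45-fold higher in CD26- cells. The inflammatory mediators CXCL8 and IL1B stood at -2.18 (SE 0.41) and -1.96 (SE 0.66). TGFBR2, a receptor of TGF-beta, stood at -2.17 (SE 0.52), ATF6, a sensor of stress in the endoplasmic reticulum, at -2.13 (SE 0.53), and TLR8, a receptor for single-stranded RNA, at -2.05 (SE 0.60). The survival factor BCL2L1 was at -2.04 (SE 0.34) and TM7SF2, an enzyme of sterol synthesis, at -1.95 (SE 0.50). With no gene called, all 23 of these genes were picked for being at least 2-fold apart in the same direction in both sheep. Their agreement between the sheep is therefore no separate result. When 1 array was left out at a time, 22 or 23 of them kept their direction. DQA1 turned to -0.36 without the CD26+ array of sheep 30066. That fit does not pair the arrays of a sheep, so it set CD26+ cells of sheep 10081 against CD26- cells of both sheep. On the CD26- and CD26+ arrays DQA1 stood at -0.244 and 1.873 in sheep 30066, and at -3.608 and -2.285 in sheep 10081. Leaving out 1 array also gave 0.72 to 2.41 for DQA2, -5.27 to -1.54 for MYLK and -2.73 to -1.20 for IL1B. The background model changed the size of several. Fitted on all spots, it gave -0.64 for ATF6, 3.74 for BMP7, 1.03 for IL1A, 0.79 for XDH, -1.96 for MYLK and -1.29 for TM7SF2.

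**Figure D1:**
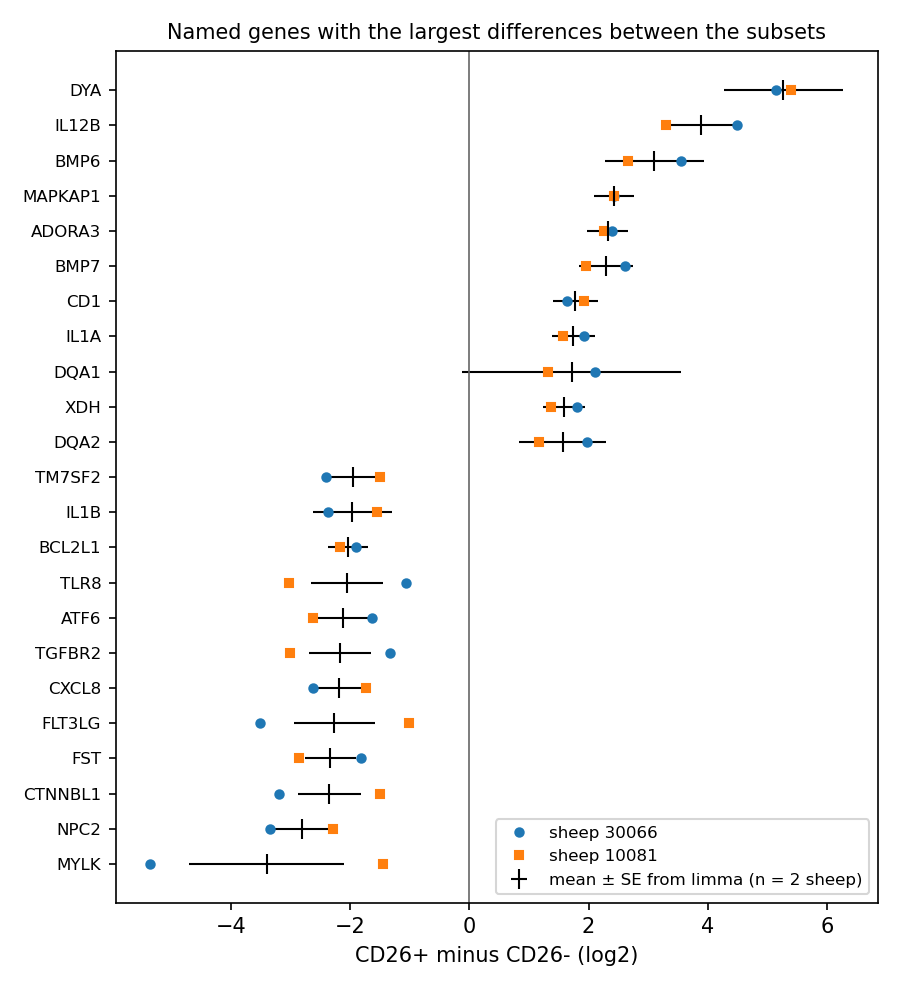
CD26+ minus CD26- on the log2 scale (horizontal axis) for 23 named genes with the largest differences of at least 2-fold in both sheep (vertical axis). Circles are sheep 30066, squares are sheep 10081, and the tick with its bar is the mean ± SE from limma; DYA lies at 5.27 and MYLK at -3.41.

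limma called 0 of 13264 probes at an adjusted p under 0.05 (smallest adjusted p = 0.765). It found 748 probes at an unadjusted p under 0.05, of which 317 were higher and 431 lower in CD26+ cells, where chance gives 663. With the sheep as a replicate block the calls stayed at 0 and 1126 probes had an unadjusted p under 0.05. On simulated data with the spread fitted here, 0 of 50 probes set 16-fold apart were called.

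Without a test, 313 probes were at least 2-fold higher in CD26+ cells in both sheep and 385 were at least 2-fold lower in both, while 267 were at least 2-fold apart in opposite directions. That is 698 in the same direction, 44.8% of them higher in CD26+ cells. Among the named genes, with 1 probe each, 18 were higher, 27 were lower and 8 went in opposite directions. Simulated data in which 13053 probes did not differ gave 448 of them in the same direction and 465 in opposite directions. The simulation left out the correlation between arrays of a sheep and gave more opposite directions than observed, so it shows the balance of directions and no expected number. The share that was higher depended on the processing. It was 34.5% with median centring in place of loess. With the background model fitted on all spots it was 61.7%, with 381 probes higher, 237 lower and 108 in opposite directions. Over all probes the differences of the 2 sheep correlated with r = 0.21, across genes, which are not independent replicates.

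**Figure D2:**
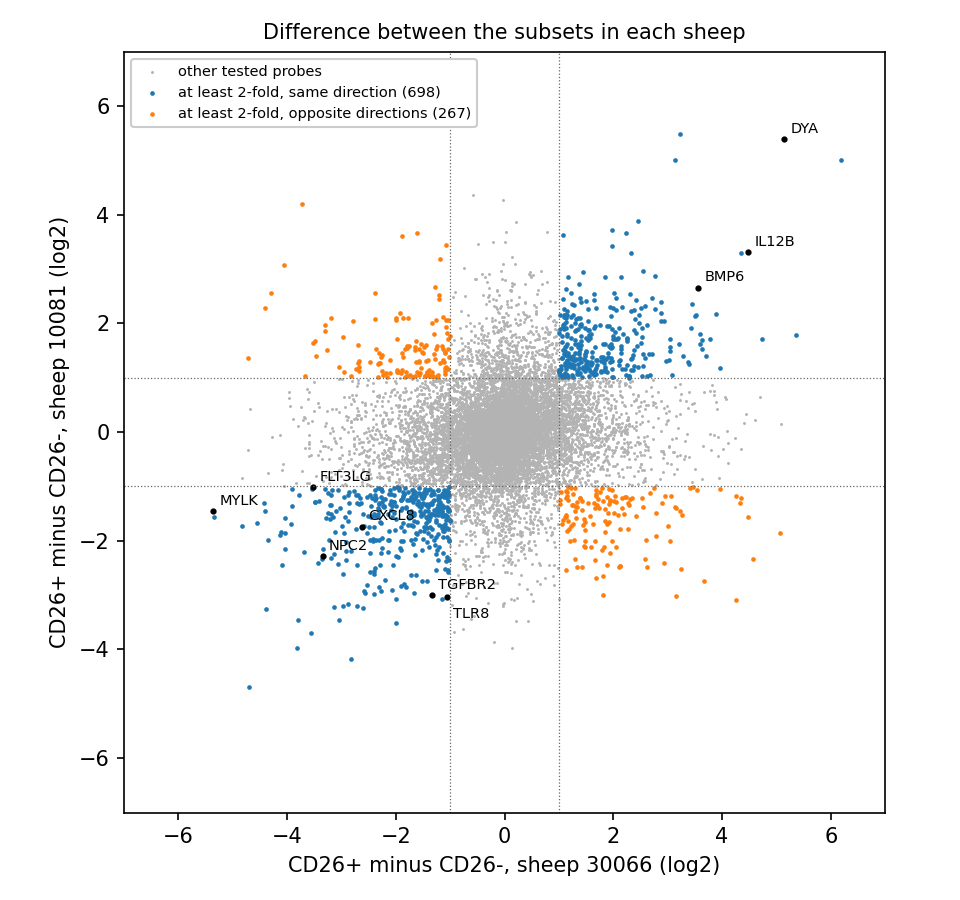
CD26+ minus CD26- on the log2 scale in sheep 30066 (horizontal axis) and sheep 10081 (vertical axis), 1 point per tested probe. Blue points are the 698 probes at least 2-fold apart in the same direction in both sheep, orange points the 267 in opposite directions, black points named genes, and dotted lines mark 2-fold.

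Genes of MHC class II presentation lay higher in CD26+ cells as a group. Of the 11 measured members, 8 were higher in CD26+ cells in both sheep, 5 of them by at least 2-fold in both, and 0 were lower in both; the median difference was 1.04. After DYA, DQA1 and DQA2, the next largest difference was that of DRA, the chain that pairs with DRB, at 1.49 (SE 0.35). The other class II chains on the list were DRB3 at 1.38, DQB1 at 1.04 and DRB1 at 0.79. The proteases on the list lay closer to 0, with CTSB at 0.18, CTSD at 0.14, LGMN at -0.10 and CTSS at -0.21. Camera with a preset correlation of 0.01 gave this list an adjusted p of 0.000366, and an adjusted p of 0.758 with an estimated correlation. The adjusted p of fry was 0.297. The estimated correlation of the members was -0.043. In a single simulated draw with independent members, a list shifted by 1 on the log2 scale was also missed by camera with an estimated correlation (adjusted p = 0.951). That setting therefore does not decide whether the list differs. No simulated result is given for fry, so its adjusted p of 0.297 is not discounted in this way. 0 members were called over all probes, and 0 adjusted over the list alone. Without the CD26- array of sheep 10081 the median was 0.52 and the camera call ended (adjusted p = 0.0770); over the alternatives that kept all subset arrays its adjusted p lay between 2.64e-05 and 0.00572.

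**Figure D3:**
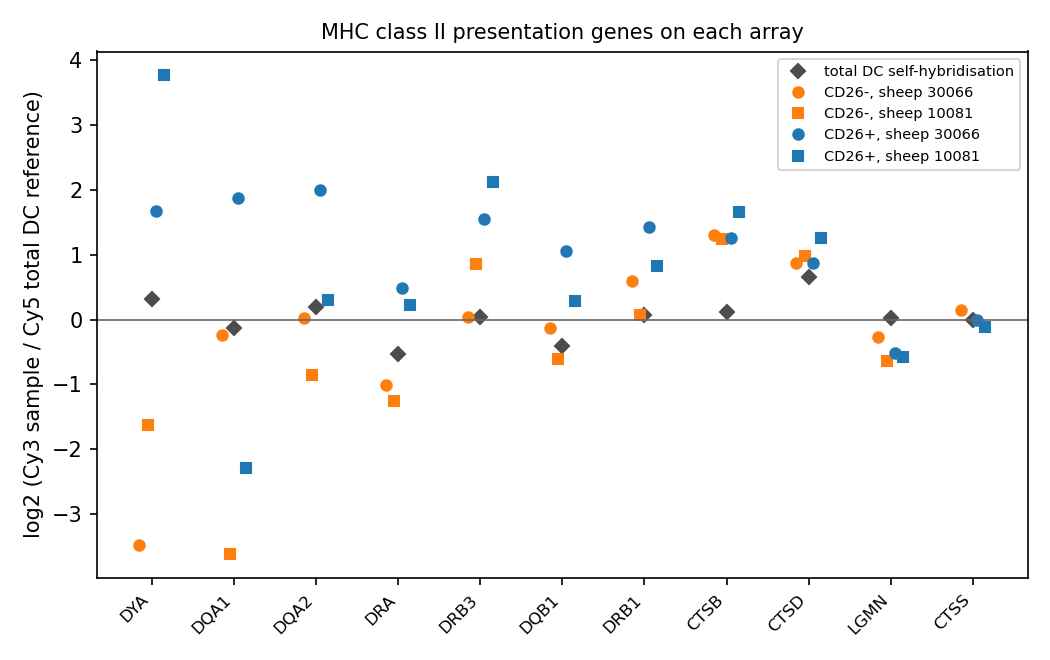
log2 of the Cy3 sample over the Cy5 total DC reference (vertical axis) for the 11 measured genes of the MHC class II presentation list (horizontal axis), 1 point per array. Blue points are CD26+ cells, orange points CD26- cells, circles sheep 30066, squares sheep 10081, and diamonds the self-hybridisation; DYA lies above 1 in both CD26+ arrays and below -1 in both CD26- arrays.

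The other 16 lists that could be tested did not pass (smallest adjusted p = 0.0600). Of the 8 measured genes of DC maturation and migration, 5 were higher in CD26+ cells in both sheep and 0 lower in both, with a median of 0.50 and a camera adjusted p of 0.0600. Besides IL12B they included the costimulatory molecule CD86, at 1.11 (SE 0.35), and TNF at 0.67 (SE 0.40), whose other probe stood at 2.29 and which was at 0.36 to 0.97 leaving out 1 array and at 1.92 with the background model fitted on all spots. This list passed with the background model fitted on all spots (adjusted p = 0.0172) and without background subtraction (0.0485); its adjusted p ranged up to 0.115 over the other alternatives that kept all arrays, and from 0.0806 to 0.233 leaving out 1 array. Of the 9 measured markers of conventional DC of type 2 (cDC2), 6 were lower in CD26+ cells in both sheep and 3 higher, with a median of -0.98 and a camera adjusted p of 0.0600. Besides TLR8 and IL1B they included FCER1A, the alpha chain of the IgE receptor, at -1.64 (SE 0.36) and well above background on 1 of 2 CD26+ arrays, and the lectin CLEC6A at -1.13 (SE 0.54; -1.62 to -0.64 leaving out 1 array). The cDC2 list passed without background subtraction (adjusted p = 0.0485) and without the CD26+ array of sheep 30066 (0.0161), reached 0.618 without another array, and lay between 0.0485 and 0.315 over the alternatives that kept all arrays. With an estimated correlation the adjusted p of both lists was 0.758. Of the 4 measured markers of type 1 (cDC1), 2 were higher and 2 lower in CD26+ cells in both sheep; IL12B was the largest and TLR3 stood at -1.09 (SE 0.62; -1.85 to -0.32 leaving out 1 array).

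Pattern recognition receptors were lower in CD26+ cells in both sheep for 7 of 14 measured members and higher for 4, with a median of -0.29 (adjusted p = 0.334). Besides TLR8 they included CLEC4E, a lectin that binds mycobacterial glycolipid, at -1.80 (SE 0.59; -2.48 to -1.12 leaving out 1 array), which was well above background on 1 of 2 CD26+ arrays. Scavenger, Fc and complement receptors had a median of -0.65 over 5 measured members (adjusted p = 0.308). Among 6 chemokines and chemokine receptors, 2 were higher and 3 lower in both sheep, with CXCL10 at 1.53 (SE 0.86) and the receptor CXCR4 at 1.08 (SE 0.45) opposite CXCL8, and the adjusted p was 0.984. Leaving out 1 array gave 0.46 to 2.60 for CXCL10 and 0.72 to 1.44 for CXCR4. Adjusted over the list alone, 1 member was called in each of 4 tested lists: IL12B among cDC1 markers and among genes of DC maturation, CXCL8 among chemokines, and FCER1A among the scavenger, Fc and complement receptors.

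No list of markers of other cell types passed the test. Of 6 markers of monocytes and macrophages, 4 were lower in CD26+ cells in both sheep and 1 higher, with a median of -0.52 (adjusted p = 0.334); CD14 stood at -1.10 (SE 0.60), the fatty acid carrier FABP5 at -1.07 (SE 0.69) and CHI3L1 at -0.79 (SE 0.39). Leaving out 1 array gave -1.84 to -0.36 for CD14 and -1.78 to -0.37 for FABP5. CHI3L1 turned to 0.56 and CD3D to 0.26 with the background model fitted on all spots, which gave -0.59 for GATA3. Of 10 T cell markers, 2 were higher and 3 lower in both sheep, with a median of 0.016 (adjusted p = 0.984). CD5 stood at 1.57 (SE 0.53) and CD247, the zeta chain of the T cell receptor complex, at 1.35 (SE 0.55), against -1.12 (SE 1.43) for CD3D and -1.57 (SE 0.93) for GATA3. The SE of CD3D includes its difference in level between the sheep. On the CD26- and CD26+ arrays CD3D stood at 1.41 and 0.10 in sheep 30066, and at 4.11 and 3.18 in sheep 10081. Leaving out 1 array gave 0.98 to 2.16 for CD5, 0.77 to 1.93 for CD247, -2.66 to 0.42 for CD3D and -2.84 to -0.29 for GATA3. The 4 measured markers of skin stroma and epithelium had a median of -0.0095 (adjusted p = 0.984). 7 lists had fewer than 3 measured members and were not tested. CLDN1, a tight junction protein counted as a Langerhans cell marker, stood at -1.25 (SE 0.35), and GNLY, a granule protein of NK and T cells, at 3.24 (SE 0.49), with a value for the difference in sheep 30066 alone. The other 3 probes of GNLY gave 0.78 to 1.11, and the background model fitted on all spots gave 1.03 for the first. Against total DC the first probe of GNLY was lower in both subsets, at -2.04 in CD26+ cells and at -5.28 in CD26- cells. CLDN1 was called adjusted over its list of 2 measured members and not over all probes. For GNLY the CD26- value rests on 1 array, so no call is given. TBX21, the other measured NK cell marker, stood at 0.14. The 2 erythroid markers had a median of 0.16, and the single measured plasmacytoid DC, B cell and neutrophil markers stood at 0.089, 0.15 and -0.095.

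The remaining tested lists did not pass with all arrays. The 16 measured cytosolic ribosomal proteins had a median of -0.0082, the 8 glycolysis genes -0.033 with the glucose transporter SLC2A1 at -1.30 (SE 0.63; -1.98 to -0.62 leaving out 1 array), and the 10 immediate early and stress genes -0.26. The 7 actin cytoskeleton genes stood at -0.36, the 5 genes of MHC class I presentation at -0.048, the 3 cell cycle genes at -0.033 with the histone H2AZ1 at 1.30 (SE 0.46), and the 3 interferon-stimulated genes at 0.89. The interferon median was 0.030 to 1.75 leaving out 1 array, and that list passed without the CD26- array of sheep 30066 (adjusted p = 0.000597; 0.349 to 0.663 in all other settings). With all arrays the adjusted p of these lists by camera at the preset correlation lay between 0.408 and 0.984. The estimated correlation of the 3 interferon-stimulated genes was 0.92, and camera with it gave an adjusted p of 0.990. The preset correlation of 0.01 thus counts them as nearly separate. CD1B, one of the sort markers, was at -0.31 (SE 0.58), with -0.86 to 0.24 when single arrays were left out. CD26 itself, encoded by DPP4, was in the rule for named genes but was not analysed here, so the values given here are no check of the sort for CD26.

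The second comparison set CD26+ DC against total DC, using the self-hybridisation array to remove dye effects. CD26+ cells had higher values than total DC for the cytokine genes IL12B and TNF and for the growth factors BMP6 and BMP7. They had lower values for CXCL8, IL1B and most ribosomal protein genes. BMP7 was well above background on 2 of 2 CD26+ arrays and not in total DC, so no size is given for it. Among the other named genes on the higher side were CLDN4, a tight junction protein, at 4.37 (SE 0.60), IL12B at 4.12 (SE 0.77), BMP6 at 4.06 (SE 1.01), the cytokine TNF at 3.98 (SE 0.49), with 2.70 for its other probe, and CLDN3 at 3.46 (SE 0.41). On the lower side were CXCL8 at -3.94 (SE 0.50), the growth factor NRG1 at -3.82 (SE 1.75), IL1B at -3.76 (SE 0.81), CLEC4E at -3.51 (SE 0.72), CTNNBL1 at -3.40 (SE 0.64) and FABP5 at -3.29 (SE 0.85). NRG1 was at -5.62 to -2.01 leaving out 1 array, and CLEC4E was well above background on 1 of 2 CD26+ arrays. These genes were picked for being at least 2-fold from the self-hybridisation in the same direction in both sheep, so that is no separate result. The lists were not tested against total DC, and both sheep and both subsets are set against the same self-hybridisation array, which by itself favours the same direction. By lists, 13 of 16 ribosomal protein genes were lower in both sheep and 3 higher, with RPL13 at -1.86 (SE 0.53) and RPS26 at -1.73 (SE 0.42). RPL32 differed most of the 16 and lay higher. Its log ratio was 1.77 on the CD26+ array of sheep 30066, 2.22 on that of sheep 10081 and -0.001 on the self-hybridisation. Of the 11 class II presentation genes 8 were higher in both and 1 lower. The glycolytic enzymes PFKL and ALDOA stood at 3.37 (SE 0.48) and 3.08 (SE 0.61), and the immediate early genes JUNB and JUND at 2.64 (SE 0.61) and 2.57 (SE 0.57). FCER1A stood at -3.08 (SE 0.44), well above background on 1 of 2 CD26+ arrays, and the proteasome activator PSME2 at -1.86 (SE 0.50). CD1B was at 0.18 (SE 0.71; -0.25 to 0.61 leaving out 1 array).

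limma called 0 of 13204 probes in this comparison (smallest adjusted p = 0.305), with 1493 at an unadjusted p under 0.05, 802 higher and 691 lower, where chance gives 660. The self-hybridisation is a single array and was assumed to vary like the subset arrays. When the mean log ratio was tested against 0 without that array, which leaves dye effects in place and counts no spread of the reference, 1165 probes were called.

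The third comparison set CD26- DC against total DC in the same way. CD26- cells had higher values than total DC for TNF, the tight junction gene CLDN4 and most immediate early genes. They had lower values for the class II chain DYA, the costimulatory molecule CD86 and most ribosomal protein genes. Named genes on the higher side were IGFBP-4, which binds insulin-like growth factors, at 4.03 (SE 0.48), CLDN4 at 3.92 (SE 0.60), IKKBETA, a kinase of the NF-kappaB pathway, at 3.37 (SE 1.22), TNF at 3.31 (SE 0.49) and PFKL at 3.08 (SE 0.48). The protease inhibitor PI3 stood at 3.002 (SE 0.75). The second probe of TNF stood at 0.41 in this comparison and that of IKKBETA at 2.32. With the background model fitted on all spots IGFBP-4 was at 2.08, IKKBETA at 1.46, TNF at 1.97 and PI3 at 1.75. On the lower side were NRG1 at -3.22 (SE 1.75), the fructose transporter SLC2A5 at -2.90 (SE 0.58), DYA at -2.87 (SE 1.23), the motor protein KIF5B at -2.87 (SE 0.44), AGGF1 at -2.54 (SE 0.51) and thioredoxin, TXN, at -2.50 (SE 1.12). CD86 stood at -1.74 (SE 0.43), CD247 at -2.20 (SE 0.68), CXCL8 at -1.76 (SE 0.50), IL1B at -1.80 (SE 0.81) and FCER1A at -1.45 (SE 0.44). CD247 does not stand for the 10 T cell markers, of which 3 were higher and 2 lower in both sheep. Their median was 0.61, and -0.082 without the CD26- array of sheep 10081. CD3D differed most and lay higher. Its log ratio was 1.41 on the CD26- array of sheep 30066, 4.11 on that of sheep 10081 and -0.105 on the self-hybridisation. DYA was well above background on 1 of 2 CD26- arrays. Leaving out 1 array gave -3.48 to -1.53 for TXN and -2.56 to -1.03 for IL1B. The fit on all spots gave -1.44 for SLC2A5, -1.25 for DYA, -1.19 for AGGF1 and -0.80 for FCER1A. Of the 11 class II presentation genes 4 were higher and 5 lower in both sheep, with a median of 0.043 that changed sign in 6 of the other settings. 13 of 16 ribosomal protein genes were lower in both sheep and 2 higher, with RPL6 at -1.75 (SE 0.47), and PSME2 stood at -1.81 (SE 0.50). RPL32 again differed most of the 16 and lay higher, with log ratios of 0.358 and 3.19 on the CD26- arrays of sheep 30066 and 10081. Of the 10 immediate early and stress genes 7 were higher in both sheep and 1 lower, with JUNB at 2.76 (SE 0.61), JUND at 2.56 (SE 0.57) and FOS at 1.53 (SE 0.92; 0.56 to 2.50 leaving out 1 array). ALDOA stood at 2.98 (SE 0.61), and CD1B at 0.49 (SE 0.71; -0.060 to 1.04 leaving out 1 array).

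limma called 0 of 13204 probes here too (smallest adjusted p = 0.350), with 1400 at an unadjusted p under 0.05, 829 higher and 571 lower, where chance gives 660. That count was 917 without the CD26- array of sheep 10081 and 636 with the background model fitted on all spots. Tested against 0 without the self-hybridisation, 1074 probes were called. At least 2-fold from the self-hybridisation in the same direction in both sheep were 2434 probes in CD26+ and 2309 in CD26- cells, against 117 and 110 in opposite directions. Both sheep were set against the same self-hybridisation array. Simulated arrays without any difference gave a median of 887 probes in the same direction and 78.5 in opposite directions over 100 draws. The simulation gave the self-hybridisation the spread fitted to the subset arrays. The log ratios of the real self-hybridisation had an SD of 0.29, with 128 probes at least 2-fold from the reference. The 887 may therefore be too high. Part of the excess may come from the shared array, and how much was not settled.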

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

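The removals of a shared departure and of a GC trend and the comparison of sample splits were chosen after the data had been seen, when the uncorrected ratio of 2.61 was known. For 8 of the 23 named genes with the largest differences, both CD26+ arrays lay on one side of the total DC self-hybridisation and both CD26- arrays on the other, each by more than 0.29, the SD of the self-hybridisation log ratios. CD26+ minus CD26- was 5.27 for DYA, 2.43 for MAPKAP1 and 1.59 for XDH, where CD26+ cells lay above and CD26- cells below total DC. It was -2.04 for BCL2L1, -2.05 for TLR8, -2.34 for FST, -2.82 for NPC2 and -3.41 for MYLK, where CD26+ cells lay below and CD26- cells above. DYA stood at 2.40 in CD26+ and -2.87 in CD26- cells against total DC, and MYLK at -1.21 and 2.19, with 4.05 and 0.33 in the CD26- arrays of sheep 30066 and 10081. These genes were picked for their large differences, and the opposite signs were not tested as such; limma called 0 probes in the direct comparison, with 748 at an unadjusted p under 0.05. FST was not well above background in CD26+ cells, so its value is no exact size and its place below total DC is uncertain.

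More probes were at least 2-fold apart between the subsets in the same direction in both sheep (698) than in opposite directions (267). A departure from the reference that the 4 subset arrays share with different strength is argued against, since the ratio was 2.58 after each array's slope on the mean of the 4 arrays was removed. GC content of the probes is argued against in the same way, with a ratio of 2.50 after a smooth trend was removed from each sheep's difference. A structure of the arrays unrelated to the subsets stays open: 386 probes were at least 1 log2 unit apart without overlap when the arrays were split by subset and 144 when the split crossed subset and sheep, but this ratio of 2.68 restates the pattern, and the split by sheep gave 761. A difference between CD26+ and CD26- cells may account for the excess as a hypothesis, and a difference in how the 2 gates were collected or processed stays open and was not tested.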

How the results depend on the processing

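The fit of normexp on all spots, the shared departure and the GC trend were chosen after seeing the data, as was the reported fit without the spots beside bright specks. CD26+ against CD26- gave 0 calls under every setting, with 658 to 1126 probes at an unadjusted p under 0.05 (547 to 999 leaving out 1 array), the highest with the replicate block, which changed no call. Against total DC the calls stayed at 0 except with the mean log ratio against 0, which drops the spread of the self-hybridisation by construction (1165 for CD26+ and 1074 for CD26-). The block and trend fits give no count of 2-fold probes, and with an array left out 1 sheep has no difference; in all other settings 618 to 722 probes were 2-fold apart in both sheep (694 without the shared departure, 686 without the GC trend). Of the 23 named genes with the largest differences, 23 kept their direction wherever all were measured, 21 of 21 with the strict filter and 22 to 23 leaving out an array, when the lone sample is assumed to vary like the others. The 2 filter settings, the intensity trend and the replicate block leave the estimates of these genes unchanged. Keeping the direction under those settings was therefore fixed in advance and is no test. With normexp on all spots 17 of the 23 were still 2-fold in both sheep, against 21 to 23 in other settings that measured them all. No background subtraction and the scanner's signals gave ratios of same to opposite directions of 2.47 and 2.73, near the reported 2.61, and normexp on all spots 5.72. The random replicate block could not be fitted: duplicateCorrelation gave a correlation for 0 probes. Aquantile scaling leaves log ratios as they are, so it tests nothing. Median centring moved the median of all tested probes by -0.24 (CD26+) and -0.20 (CD26-) against total DC, and values under it are relative to that.

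The lists past the threshold numbered 1 in the reported processing, 3 without background subtraction, 2 with normexp on all spots, and 0 to 2 leaving out an array; the cause was not tested. List medians of CD26+ minus CD26- changed sign as follows, in lists that passed no test either way; the cause was not tested. cDC1 markers were at -0.019 without background subtraction and -0.20 with normexp on all spots. Ribosomal proteins were at 0.070 with the scanner's signals and the deposited table, which repeats them, 0.040 with median centring and 0.051 with normexp on all spots. T cell markers were at -0.017 with median spot signals. With median centring chemokines were at 0.0019 and glycolysis at 0.000117. With normexp on all spots monocyte and macrophage markers were at 0.090, skin stroma at 0.032, CHI3L1 at 0.56 and CD3D at 0.26. Against 0, CD1B was at -0.56 in CD26+ and -0.25 in CD26- cells. Leaving out 1 array gave medians from -0.28 to 0.41 for MHC class I presentation, -0.35 to 0.47 for T cell markers, -0.32 to 0.0093 for actin genes, -0.11 to 0.15 for cDC1 markers, -1.66 to 1.59 for cell cycle genes, -0.17 to 0.14 for chemokines, -0.11 to 0.094 for ribosomal proteins, -0.20 to 0.062 for glycolysis, -0.64 to 0.44 for immediate early genes, -1.04 to 0.065 for scavenger receptors and -0.20 to 0.17 for skin stroma. It gave -0.36 to 3.80 for DQA1, -0.86 to 0.24 for CD1B and -2.66 to 0.42 for CD3D between the subsets, and -0.25 to 0.61 and -0.060 to 1.04 for CD1B in CD26+ and CD26- cells against total DC. The fits leaving out 1 array do not pair the arrays of a sheep, so their ranges include differences between the sheep. Signal over background limits the 1744 dim probes left out.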

Other observations

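The tests on sheep 10081 and on the reference in this part were chosen after the result was seen. Probes that the array describes as MHC class I or class II gave a wider view of antigen presentation than the lists. This grouping was made before values were seen and after the planned lists. Of 10 MHC class II probes, 10 were higher in CD26+ than in CD26- cells in both sheep and 6 by at least 2-fold in both, with a median difference of 1.34. The adjusted p over 5 such groups was 4.54e-08 by camera, 0.133 with an estimated correlation and 0.0288 by fry. With the sheep as a replicate block, the alternative that gave 1126 probes at an unadjusted p under 0.05, the adjusted p of fry was 0.144. Most of these class II probes are also in the class II list of the report. Of 15 MHC class I probes, 14 were higher in CD26+ cells in both sheep, with a smaller median of 0.57. The adjusted p was 0.00148 by camera, 0.715 with an estimated correlation and 0.632 by fry. The estimated correlation of these 15 probes was 0.92. Camera at the preset correlation thus counts them as nearly separate. Neither its adjusted p nor the count of 14 rests on separate measurements. The 5 measured genes of the MHC class I presentation list had a median of -0.048. The 36 T cell receptor probes had a median difference of 0.19, the 82 immunoglobulin probes 0.00178 and the 6 probes of T19 (WC1), a marker of gamma delta T cells, -0.025 (adjusted p by camera 0.0962, 0.602 and 0.958). T19 probes lay below the reference on the 4 subset arrays, with medians of -0.62 to -0.70, and at -0.14 on the self-hybridisation.

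Immunoglobulin and T cell receptor probes were more often higher in sheep 10081 than in sheep 30066. The 118 measured probes of this kind include some with no value on a subset array, and shares leave those out. Of the rest, 18.6% were at least 1 log2 unit higher in both subsets of sheep 10081 than in both of sheep 30066. The other way it was 0.885%. All probes also leaned towards sheep 10081, with 4.26% meeting the same rule and 1.62% the other way. A general shift of the arrays of sheep 10081 is argued against only as the whole account, since all probes met the rule 4.36 times less often. Some immunoglobulin probes share a transcript, so the share does not rest on separate genes alone. T cell receptor probes by themselves met the rule no more often than all probes. Whether T cells were among the sorted cells of sheep 10081 is not decided by the fixed T cell markers. Of the 7 that were well above background in both its arrays, 4 (57.1%) were higher in both arrays of sheep 10081. Other sources of immunoglobulin were not tested. CD3D stood at 4.11 and 3.18 on its CD26- and CD26+ arrays, against 1.41 and 0.10 in sheep 30066, while CD247 stood at -2.53 and -1.45 in sheep 10081. The sort for CD1b should exclude T cells, and slide row and sheep cannot be told apart.

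Both subsets tended to lie on the same side of the total DC reference. All 4 subset arrays were at least 1 log2 unit above the self-hybridisation for 729 probes and below it for 488, while for 28 probes the reference lay between the subset means by at least that much. The first kind was 43.5 times as frequent, which restates the pattern and does not decide whether total DC is a mixture of cells like those sorted. Part of it may come from the single self-hybridisation array that all 4 share. Over 100 simulated draws without differences the median was 306 such probes and the highest count 366, against 1217 observed. The simulation gave the self-hybridisation the spread fitted to the subset arrays, while the real one had an SD of 0.29. The simulated counts may therefore be too high. Cell handling during the sort, as shown by immediate early and stress genes, stays open: 4 of 10 measured genes (40.0%) were above the reference on all 4 arrays, among them JUNB and JUND, and the others were not. By the sample labels the reference came from other sheep, and by the labelling protocol from a cultured cell line; neither source of a difference was tested.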
